A study of Mus musculus with 6 samples.

How the data were processed

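Total RNA was taken from the right cortex of 6 mice, 3 given vehicle and 3 given resveratrol, and libraries were made with a stranded total RNA kit after removal of ribosomal RNA, per the labels' protocols. The design text gives 3 mice per group, so the 6 libraries were treated as 6 separate animals. Groups and replicate numbers were taken from the sample titles. STAR (an aligner), Cufflinks and Cuffdiff (tools that estimate and compare transcript abundance) and the build GRCm38 are listed in the submitters' processing notes, with no version or role. The annotation, the filter behind the list of genes, and whether strand was used are not given in the sources used here.

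The deposited table holds 13582 gene rows. Its 6 library columns are FPKM (fragments per kilobase of transcript scaled to the mapped fragments of the library) that the authors computed, per the file headers. No value is 0 in it: 35 values in 23 genes stand at exactly 0.01, which was read as a floor. The authors also deposited log2 group values, a log2 fold change of resveratrol over vehicle, and a p-value and q-value per gene, per the file headers. The deposited q-values equal the Benjamini-Hochberg adjustment of the p-values over the listed genes to within 5.20e-07. The deposited log2 group values follow the mean of the libraries, except in 12 genes where they are off by more than 0.1, and 6 of the 11 of these with sequence data share over 50% of their 50-base words with other genes. A total of 23 gene names had turned into dates in the deposited table, and these rows count in totals but are not named. Another 16 rows name 2 or more genes, and the row called Eif3j1 is one of them, named for Eif3j1 and Eif3j2 at the same locus as the row of Eif3j2 alone. There are 2 values that read as failed, and their genes were left out of the tests. The loci in the table overlap the GRCm38 gene of the same name in only 15.2% of matched rows, so those loci were not used. Coordinates are printed from GENCODE M21 (GRCm38), to which 13054 rows (96.1%) were matched by name. No mitochondrial rows are listed, so the list of mitochondrially encoded subunits gave no value.

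Depth could not be recovered. Low FPKM values of genes with 1 transcript, scaled by transcript length, were compared with multiples of many trial steps. At the best step of each library, 29.6% to 33.7% of them lay within 0.1 of a whole number. Chance gives 20% for 1 step and more for the best of many, a level that was not computed. No interval from counting error is therefore given.

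FPKM is not a count, so genes were tested with limma (version 3.58.1, R 4.3.3) on log2(FPKM + 0.5), with an intensity trend in the empirical Bayes step, for genes with a mean of at least 0.5 FPKM. Fold changes are on this scale, which understates the change of genes with low values. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over 13574 genes, with a threshold of 0.05. Printed errors are SD for group means and SE for log2 fold changes. Gene lists were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. Of 40 lists fixed before the data were examined, 39 had at least 5 measured members, and their adjusted p is over these 39. Camera with an estimated correlation and fry were run beside it. The scripts were tested on simulated data for this comparison over 13574 genes, in 10 runs with 200 changed genes each. They recovered 74.7% of genes changed by 1 on the log2 scale and 96.9% of those changed by 2, and 3.64% of the calls were false. At an unadjusted p under 0.05, a list of 30 genes shifted by 0.3 was called in 10 of 10 runs with the preset. With the estimated correlation it was called in 10 of 10, and an unshifted list was called in 0 with the preset. The simulated genes varied independently. These runs therefore do not gauge calls of real lists whose members vary together, such as oxidative phosphorylation (estimated correlation 0.819).

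Genes were named by a rule fixed before the data were examined. It takes up to 12 genes in each direction, first those past the threshold with the largest fold and then those with the smallest p, whose groups do not overlap. It adds up to 4 members with the smallest p of each list past the threshold and up to 2 of each other list, 10 genes of resveratrol and preconditioning research, and the 10 genes with the largest folds in each direction of the authors' table. Predicted gene models and small RNAs were counted but not named under it. The share of a gene's 50-base words found in other genes was computed from GENCODE M21 transcripts.

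Alternatives fixed beforehand were pseudocounts of 0.1 and 1, no filter and a filter at 2 FPKM, median centring, quantile normalization, robust empirical Bayes, sample weights, the replicate number as a block, a threshold of 0.1, each library left out, and the estimated correlation and fry for lists. Chosen after seeing the data were a loess correction of each library on transcript length and GC content (span 0.3), a fit without vehicle 1 and 2, and counts of the authors' table at q 0.1 and without overlap. Count-based tests were not run, since no column holds counts. The estimate of the sample weights did not converge. It put 5.02 on vehicle 1 and 9.20 on resveratrol 2 against at most 0.556 elsewhere. Gene and list values with sample weights therefore rest mostly on these 2 libraries.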

Results

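The series asks what the transcriptome of the mouse cortex looks like in the late period of tolerance to ischemia that follows preconditioning with resveratrol, a plant polyphenol. RNA was sequenced from the right cortex of 6 C57BL/6 mice, aged 10 weeks at sacrifice, 2 weeks after 1 intraperitoneal injection. Of these, 3 mice had received vehicle and 3 resveratrol at 10 mg/kg, and no ischemia is named in the labels of these samples. The dose field of the vehicle samples also reads 10 mg/kg, and it was taken from the treatment text that these mice received no resveratrol. The table lists 13582 genes in FPKM, and 13574 of them entered the test. The listed FPKM summed to between 351731 (vehicle 2) and 397876 (resveratrol 3), and the median gene lay between 9.84 and 10.2 FPKM in each library. The sequencing depth per library is unknown, since the low values did not fall on steps of whole reads.

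The libraries did not separate by treatment along the main axis of variation. Pearson's r between libraries, across genes, ranged from 0.975 to 0.990. The first principal component held 43.2% of the variance and placed vehicle 1 (-16.4) and vehicle 2 (-25.8) apart from vehicle 3 (18.8) and from resveratrol 1 (9.63), resveratrol 2 (1.41) and resveratrol 3 (12.3). In some libraries the deviations followed transcript length, with a Spearman correlation across genes of 0.310 in vehicle 1, 0.474 in vehicle 2, -0.502 in vehicle 3 and -0.327 in resveratrol 3, against 0.00286 in resveratrol 1 and -0.135 in resveratrol 2. With GC content the correlation was -0.343, 0.0561 and -0.0354 in vehicle 1, 2 and 3, and -0.463, 0.227 and 0.567 in resveratrol 1, 2 and 3.

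The comparison of resveratrol with vehicle asks which genes remain altered in the cortex 2 weeks after the injection. A single gene row passed the limma test. Eif3j1, a subunit of the translation initiation factor eIF3, rose from 0.106 ± 0.0181 FPKM in vehicle to 12.6 ± 1.96 FPKM in resveratrol (SD, n = 3 each). Its log2 fold change was 4.42 ± 0.15 (SE), its limma adjusted p was 1.53e-06, and all 3 resveratrol libraries lay above all 3 vehicle libraries. The Eif3j2 row had 17.7 ± 1.16 FPKM in vehicle and 5.42 ± 3.23 FPKM in resveratrol and did not pass. In the deposited table the row called Eif3j1 here is named for both Eif3j1 and Eif3j2, and both rows carry the same locus. The GRCm38 annotation places Eif3j1 on chromosome 2 from 122028546 to 122056598 and the gene Eif3j2 on another chromosome, so which transcripts each row holds is not settled. In that annotation 91.9% of the 50-base words of Eif3j2 and 39.8% of those of Eif3j1 also occur in other genes, and the call of Eif3j1 is reported as uncertain. The FPKM of both rows added together was 17.8 ± 1.17 in vehicle and 17.98 ± 1.37 in resveratrol (SD, n = 3 each; exact permutation test, two-sided, p = 0.8, where 0.1 is the smallest p that 3 against 3 allows). In limma 0 genes were lower, and the smallest adjusted p of any gene other than Eif3j1 was 0.987. An unadjusted p under 0.05 was found for 329 genes (222 higher and 107 lower) where chance gives 679. The balance of directions moved with the setting. It was 144 higher and 138 lower with median centring, 101 and 143 without resveratrol 3, and 297 and 107 without resveratrol 1.

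**Figure D1:**
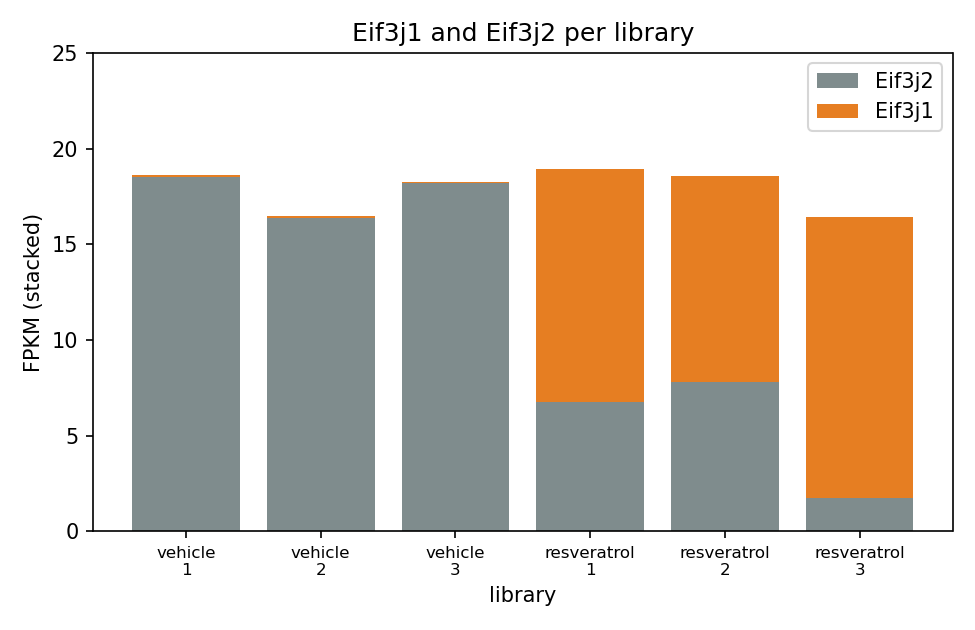
Stacked bars show the FPKM of Eif3j2 (grey) and Eif3j1 (orange) in each of the 6 libraries, on an axis that starts at 0. Eif3j1 lies between 0.0926 and 0.126 FPKM in the vehicle libraries and between 10.8 and 14.7 FPKM in the resveratrol libraries, while the total of both stays between 16.4 and 19.0 FPKM.

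None of the other genes named here passed the threshold, and their values are given as measured. Of the genes with the smallest p and no overlap between groups, those higher in resveratrol included 4 genes for the core histone H3. Hist1h3a had 2.29 ± 0.95 FPKM in vehicle and 5.26 ± 0.997 FPKM in resveratrol (log2 fold change 1.08 ± 0.23 SE, n = 3 each), and the log2 fold changes of Hist1h3h, Hist1h3i and Hist2h3b were 0.95, 0.70 and 0.64. Between 49.5% and 93.9% of the 50-base words of these histone transcripts occur in other genes. Also on the higher side were Mgmt, a DNA repair enzyme that removes alkyl groups from guanine (0.71 ± 0.17), Tspo, a protein of the outer mitochondrial membrane (0.80 ± 0.23), Sdf2l1, a protein of the endoplasmic reticulum induced by unfolded proteins (0.71 ± 0.18), and Pacsin3, a membrane-bending adaptor (0.49 ± 0.13). B9d2, Hsbp1l1 and Ddx23 had log2 fold changes of 0.59, 0.62 and 0.35.

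On the lower side, Scd3, a stearoyl-CoA desaturase that makes monounsaturated fatty acids, had 10.55 ± 1.70 FPKM in vehicle and 4.97 ± 2.05 FPKM in resveratrol (log2 fold change -1.08 ± 0.26 SE, n = 3 each). Col1a1, a chain of fibrillar collagen, had 1.14 ± 0.131 and 0.507 ± 0.181 FPKM (-0.72 ± 0.19). Ccdc153 (-0.81) and Tmem212 (-0.84) are genes of ciliated ependymal cells, and Aldh9a1 (-0.44) is an aldehyde dehydrogenase. Ly6c2 (-1.18), Lrrc51 (-0.54), Fam205a1 (-0.81), Fam205a2 (-0.82), Tmem181c-ps (-0.84) and Rpl31-ps12 (-1.08) completed the group. Of these, Fam205a1, Fam205a2, Tmem181c-ps and Rpl31-ps12 share between 59.8% and 100% of their 50-base words with other genes and are uncertain. Across all tested genes, 852 (6.28%) had groups that did not overlap, where chance gives 10%.

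None of the 10 genes fixed in advance for their place in resveratrol and preconditioning research passed the threshold. Sirt1, the NAD-dependent deacetylase long discussed as a target of resveratrol, had 7.20 ± 0.276 FPKM in vehicle and 7.68 ± 1.73 FPKM in resveratrol (log2 fold change 0.07 ± 0.15 SE, n = 3 each). Ppargc1a, a coactivator of mitochondrial biogenesis, differed by -0.14 ± 0.14, and Ucp2, an uncoupling protein of mitochondria, by -0.31 ± 0.22. Nfe2l2, the transcription factor of the antioxidant response, differed by 0.05 ± 0.11 and its target Hmox1 by 0.16 ± 0.20. The values of Hif1a (0.08 ± 0.12), Nampt (0.07 ± 0.13) and Bdnf (0.24 ± 0.13) were also small. The largest differences were those of the activity-regulated genes Arc (0.90 ± 0.39) and Fos (0.70 ± 0.34). On simulated data the test recovered 74.7% of genes changed by 1 on the log2 scale. Each simulated run held many changed genes, which eases the adjusted threshold. Here only Eif3j1 passed of the 20 genes that differed by more than 1, and these were picked on their measured fold. The 74.7% is therefore not a recovery rate for these libraries. The SEs of Arc and Fos also lie well above the median of 0.14 over all genes.

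Lists of genes fixed before the data were examined were then compared with all other genes. With camera at a preset correlation, 11 of 39 lists passed the adjusted threshold: 7 of 23 pathway lists (5 higher and 2 lower) and 4 of 16 cell type lists (1 higher and 3 lower). When the correlation was estimated from the libraries, 0 lists passed, and the smallest adjusted p was 0.247. Correlation between members cannot be the whole reason for this loss. The estimate for ependymal markers was -0.104, under the preset of 0.01, yet their unadjusted camera p rose from 4.03e-07 to 0.00632. The self-contained test fry also gave 0 lists, with a smallest adjusted p of 0.0675 and 3 lists at an unadjusted p under 0.05. In 37 of the lists 0 genes passed when adjusted over the list alone, and in all 39 lists 0 genes passed when adjusted over all genes tested.

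Nuclear genes of oxidative phosphorylation, the mitochondrial machinery that makes ATP, rose as a group. Of 72 measured genes 68 were higher and 4 lower in resveratrol, with a median log2 fold change of 0.15 (camera adjusted p = 3.71e-07). This call was lost at adjusted p = 0.807 with an estimated correlation. The largest evidence came from Ndufab1 (0.39 ± 0.16 SE), Atp5g2 (0.30 ± 0.13), Atp5d (0.28 ± 0.13) and Cox7c (0.35 ± 0.16), subunits of complex I, ATP synthase and cytochrome oxidase, none past the threshold. Genes of the cytosolic ribosome rose as well, with 47 of 50 higher, a median of 0.18 and a camera adjusted p of 8.92e-07 (adjusted p = 0.807 with an estimated correlation). Rpl34 (0.34), Rpl38 (0.41), Rps15 (0.33) and Rps21 (0.32) had the smallest p among its members. For both lists vehicle 2 was lowest (mean deviations -0.31 and -0.32) and vehicle 3 highest (0.22 and 0.17). Without vehicle 2 the medians were 0.03 and 0.08, at adjusted p = 0.819 and 0.410, without vehicle 3 they were 0.30 and 0.31, and with quantile normalization 0.08 and 0.10. Of the choices made after seeing the data, the length and GC correction gave 0.09 and 0.11, and with vehicle 1 and 2 left out the medians turned to -0.15 and -0.14. Over all alternatives the adjusted p ranged from 3.01e-20 to 0.854 for the first list and from 2.84e-16 to 0.854 for the ribosome.

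Genes of glycolysis rose, with 24 of 25 higher, a median log2 fold change of 0.14 and a camera adjusted p of 0.00101 (adjusted p = 0.807 with an estimated correlation). Eno1, an enolase, had 184 ± 13.3 FPKM in vehicle and 237 ± 32 FPKM in resveratrol (0.35 ± 0.13 SE, n = 3 each) without overlap of the groups, although 68% of its 50-base words occur in other genes. Pkm (0.25), Pfkp (0.16) and Pfkl (0.24), which encode pyruvate kinase and subunits of phosphofructokinase, were next. The call was lost without resveratrol 3 (adjusted p = 0.0588) and with vehicle 1 and 2 left out (a choice made after seeing the data, median 0.07, adjusted p = 0.482), in a range of 6.93e-04 to 0.807 over all alternatives. With quantile normalization the median was 0.08.

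Heat shock and unfolded protein response genes rose, with 27 of 35 higher, a median of 0.10 and a camera adjusted p of 0.00136 (adjusted p = 0.807 with an estimated correlation). In this list 7 genes had groups that did not overlap, among them Sdf2l1, the small heat shock protein Hspb1 (0.62 ± 0.20 SE, uncertain since 51.6% of its 50-base words occur in other genes), the co-chaperone Dnajb5 (0.29 ± 0.10) and Hspa5, the main chaperone of the endoplasmic reticulum (0.24 ± 0.12). The call was lost without vehicle 2 (adjusted p = 0.0678), with sample weights (0.193) and with vehicle 1 and 2 left out (a choice made after seeing the data, median 0.06, adjusted p = 0.308), within a range of 1.01e-04 to 0.807. With quantile normalization the median was 0.05.

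Immediate early genes, which neurons transcribe within minutes of activity, rose as a group. Of 33 measured genes 28 were higher in resveratrol, with a median log2 fold change of 0.26 (camera adjusted p = 1.58e-04, adjusted p = 0.807 with an estimated correlation). Arc, a regulator of synaptic strength, had 35.4 ± 20.1 FPKM in vehicle and 63.8 ± 26.8 FPKM in resveratrol (0.90 ± 0.39 SE, n = 3 each). Junb (0.79 ± 0.34), Dusp1 (0.78 ± 0.35), Fos (0.70 ± 0.34) and Ier5 (0.36 ± 0.16) lay on the same side, and 0 members had groups that did not overlap. Mean deviations were -0.37 in vehicle 1, -0.28 in vehicle 3 and -0.16 in resveratrol 2, against 0.23 in vehicle 2, 0.23 in resveratrol 1 and 0.35 in resveratrol 3. The call was lost without resveratrol 3 (adjusted p = 0.106), without vehicle 3 (adjusted p = 0.209) and with sample weights (adjusted p = 0.232). Without resveratrol 1 and without vehicle 1 the medians were 0.15 and 0.13, and the adjusted p of all alternatives lay between 1.11e-14 and 0.854.

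Chromatin modifiers fell as a group, with 41 of 65 lower, a median log2 fold change of -0.05 and a camera adjusted p of 0.0373 (adjusted p = 0.807 with an estimated correlation). The histone methyltransferase Setd1b (-0.55 ± 0.31 SE) was lower, while the Polycomb subunit Eed (0.28 ± 0.14) and the deacetylase Hdac8 (0.24 ± 0.13) were higher. The mean deviation was 0.24 in vehicle 2, 0.06 in vehicle 1 and -0.20 in vehicle 3. The call was lost without resveratrol 1 (adjusted p = 0.158), without resveratrol 3 (0.112, median -0.03), without vehicle 1 (0.105, median -0.03) and, chosen after seeing the data, with the length and GC correction (0.75, median 0.01). The median turned to 0.04 without vehicle 2 (adjusted p = 0.819) and to 0.16 with vehicle 1 and 2 left out, and it was -0.16 without vehicle 3. Genes of GABA signalling, the main inhibitory transmission, also fell, with 20 of 23 lower, a median of -0.06 and a camera adjusted p of 0.0397 (adjusted p = 0.807 with an estimated correlation). The receptor subunit Gabra2 (-0.28), the synthesising enzyme Gad2 (-0.26) and the vesicular transporter Slc32a1 (-0.26) were lower, and the receptor subunit Gabrd (0.26) was higher. This call was lost without resveratrol 2 (adjusted p = 0.0527), resveratrol 3 (0.30, median -0.03), vehicle 1 (0.295) or vehicle 2 (0.191, median -0.04), with the length and GC correction (0.217, median -0.04) and with vehicle 1 and 2 left out (0.482, median 0.05). The median was -0.09 without resveratrol 1, -0.10 without vehicle 3 and with sample weights, and -0.11 with quantile normalization. Adjusted p over all alternatives ranged from 2.35e-06 to 0.862 for chromatin modifiers, where the lowest belongs to the fit with vehicle 1 and 2 left out and so to the opposite direction, and from 0.00588 to 0.854 for GABA signalling.

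**Figure D2:**
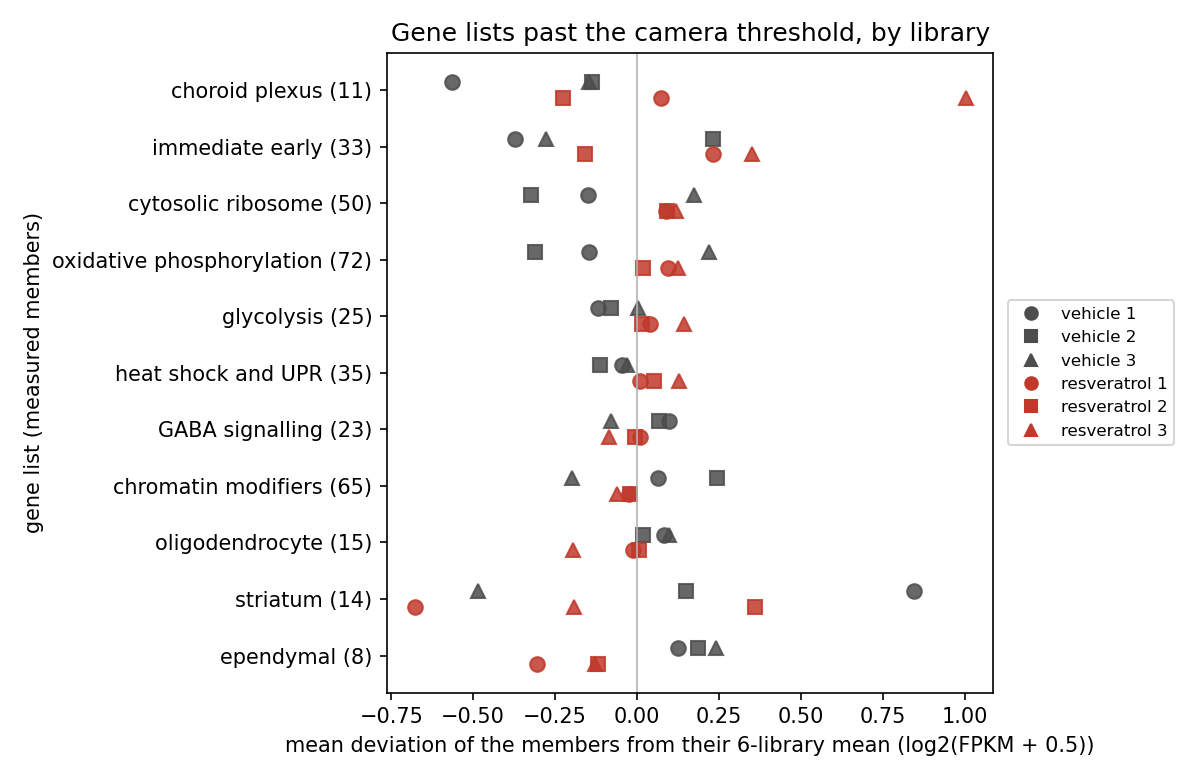
Each row is a gene list past the camera threshold, and each point is a library (grey vehicle, red resveratrol, symbols for replicate 1 to 3) at the mean log2(FPKM + 0.5) deviation of the list's members from their 6-library means. Striatal markers range from 0.84 in vehicle 1 to -0.68 in resveratrol 1, choroid plexus markers reach their highest value in resveratrol 3, and vehicle 2 is lowest for oxidative phosphorylation (-0.31) and the ribosome (-0.32).

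Among markers of cell types and neighbouring regions, those of ependymal cells, the ciliated lining of the ventricles, fell. All 8 measured genes were lower, with a median log2 fold change of -0.27 and a camera adjusted p of 5.24e-06 (adjusted p = 0.247 with an estimated correlation). Adjusted over the list alone 2 genes passed, Ccdc153 (1.80 ± 0.196 FPKM in vehicle and 0.823 ± 0.218 FPKM in resveratrol, SD, n = 3 each) and Tmem212 (1.45 ± 0.285 and 0.592 ± 0.160 FPKM), and 0 passed over all genes. Rarres2, which encodes chemerin, differed by -0.45 ± 0.17 (SE) without overlap of the groups, and Dynlrb2, a light chain of dynein, by -0.21 ± 0.17. The list passed without any single library, and its median was -0.09 without resveratrol 1. Adjusted p ranged from 2.37e-07 to 0.247 over the alternatives that gave a value. The filter at 2 FPKM gave none for this list, so whether the fall holds without genes of low FPKM was not tested.

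Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid, rose, with all 11 higher, a median of 0.50 and a camera adjusted p of 1.34e-04 (adjusted p = 0.807 with an estimated correlation). Ttr, the thyroxine carrier transthyretin, had 56.0 ± 48.2 FPKM in vehicle and 207 ± 208 FPKM in resveratrol (1.75 ± 0.84 SE, n = 3 each), and resveratrol 3 alone had 441 FPKM. The potassium channel subunit Kcne2 (0.82), the folate receptor Folr1 (0.91) and Calml4 (0.68) followed. Without resveratrol 3 the median was 0.10 and the adjusted p 0.364, and with sample weights 0.22 and 0.335, in a range of adjusted p from 1.80e-13 to 0.854. Without resveratrol 2 the median was 0.80. The filter at 2 FPKM gave no value for this list, and Kcne2, Folr1 and Calml4 had 0.243, 0.565 and 0.752 FPKM in vehicle.

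Striatal markers fell, with all 14 lower, a median of -0.33 and a camera adjusted p of 3.65e-04 (adjusted p = 0.807 with an estimated correlation). Syndig1l had 8.87 ± 5.03 FPKM in vehicle and 4.94 ± 2.78 FPKM in resveratrol (-0.73 ± 0.45 SE, n = 3 each), and Tac1 (-0.42) and Gng7 (-0.44) were lower too. Vehicle 1 was highest (mean deviation 0.84) and resveratrol 2 next (0.36). Without vehicle 1 the median was 0.02 (adjusted p = 0.734), without resveratrol 1 it was -0.14 (adjusted p = 0.464), and with vehicle 1 and 2 left out, chosen after seeing the data, it turned to 0.32, in a range of adjusted p from 1.82e-11 to 0.854. Without resveratrol 2, without vehicle 3 and with sample weights it was -0.63, -0.73 and -0.51.

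Oligodendrocyte markers fell, with 13 of 15 lower, a median of -0.11 and a camera adjusted p of 0.00155 (adjusted p = 0.807 with an estimated correlation). The myelin regulator Myrf (-0.62 ± 0.31 SE) and the myelin genes Mal (-0.23), Mog (-0.24) and Cldn11 (-0.19) were lower. The call was lost without resveratrol 3 (median -0.05, adjusted p = 0.200) and without vehicle 3 (median -0.04, adjusted p = 0.155) and with sample weights (median -0.01, adjusted p = 0.232), in a range of 2.76e-05 to 0.854. The median was -0.16 without resveratrol 1, -0.17 without resveratrol 2 and -0.21 with vehicle 1 and 2 left out.

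The remaining 16 pathway lists did not pass in camera. In metabolism and mitochondria, the citric acid cycle had a median log2 fold change of 0.08 (adjusted p = 0.199, with Idh2 at 0.25 and Pdk3 at -0.17), mitochondrial biogenesis 0.05 (0.995, Esrra at 0.34 and Stk11 at 0.23), sirtuins and NAD metabolism 0.07 (0.463, Sirt6 at 0.27 and Sirt3 at 0.21), and lipid and cholesterol metabolism 0.02 (0.648, Acadvl at 0.19 and Acly at 0.12). For stress and survival, the NRF2 antioxidant list had 0.07 (0.325, Prdx5 at 0.29 and Mt2 at -0.25), hypoxia 0.01 (0.995, Epor at 0.34 and Egln2 at 0.36), apoptosis 0.03 (0.622, Bax at 0.25 and Bak1 at 0.32), autophagy 0.04 (0.685, Park2 at 0.27 and Wipi1 at -0.26) and glucocorticoid response 0.10 (0.783, Pdk4 at -0.24 and again Mt2). For transmission and rhythm, glutamate receptors had -0.03 (0.196, Grin2d at -0.33 and Dlg4 at -0.29), synaptic vesicles -0.01 (0.287, Stx1a at 0.30 and Vamp2 at -0.54), ion pumps 0.02 (0.794, Atp2b4 at -0.38 and Atp1b2 at -0.67), neurotrophic factors -0.08 (0.354, Fgf2 at -0.55 and Bdnf) and the circadian clock 0.06 (0.294, Cry1 at 0.26 and Csnk1e at 0.22). Inflammation had 0.04 (0.623, C4b at -0.46 and Myd88 at 0.30) and the interferon response 0.06 (0.504, Isg15 at 0.29 and Ifit2 at 0.21). Some of these lists passed under an alternative. The circadian clock rose without vehicle 2 (median 0.13, adjusted p = 2.71e-04), without resveratrol 3 (0.07, 0.0486) and, chosen after seeing the data, with vehicle 1 and 2 left out (0.19, 3.69e-04), in a range of 2.71e-04 to 0.854. Without vehicle 3, glutamate receptors (median -0.13, adjusted p = 0.00170) and synaptic vesicles (-0.03, 0.0319) fell, and the citric acid cycle (0.13, 0.0315) and the NRF2 list (0.10, 0.0226) rose. Glutamate receptors and synaptic vesicles also fell with quantile normalization (-0.07, 0.0309, and -0.09, 0.0177) and glutamate receptors with sample weights (-0.15, 0.0307). With vehicle 1 and 2 left out the direction was opposite for glutamate receptors (0.14, 4.19e-04), synaptic vesicles (0.10, 0.0498) and the NRF2 list (-0.06, 0.00813). Over all alternatives the adjusted p ranged from 4.19e-04 to 0.994 for glutamate receptors, 0.0177 to 0.862 for synaptic vesicles, 0.0315 to 0.854 for the citric acid cycle and 0.00813 to 0.945 for the NRF2 list. Medians were positive while camera's direction was down for inflammation, lipid metabolism and ion pumps, and for hypoxia the mean was -0.0077 with a positive median and camera's direction up.

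The remaining 12 cell type and region lists did not pass either. Oligodendrocyte precursors were nearest, with a median log2 fold change of -0.13 (adjusted p = 0.0511, Enpp6 at -0.24 and Olig1 at -0.20). Astrocytes had -0.01 (0.199, Aldh1l1 at 0.21 and Sox9 at -0.60), microglia -0.01 (0.623, Tmem119 at 0.28 and Tyrobp at 0.29), excitatory neurons 0.10 (0.418, Neurod1 at 0.30 and Emx1 at 0.24) and inhibitory neurons -0.10 (0.323, Npy at 0.35 and Dlx2 at -0.38). Among vascular and meningeal markers, endothelial cells had 0.0012 (0.496, Slco1a4 at -0.22 and Ly6c1 at -0.30), mural cells -0.08 (0.685, Higd1b at 0.63 and Anpep at -0.29), meningeal fibroblasts 0.01 (0.339, Igfbp2 at 0.46) and blood 0.01 (0.998, Hbb-b2 at -0.35). Adjusted over the list alone 1 meningeal gene passed, Col1a1, and 0 over all genes. Hippocampal markers had -0.16 (0.287, Prox1 at -0.38 and Bok at 0.25), thalamic markers -0.02 (0.710, Prkcd at 0.27 and Lef1 at -0.50), and those of claustrum, piriform cortex and amygdala -0.08 (0.199, Gpr101 at -0.90 and Synpr at 0.16). Some of these lists passed under an alternative too. Oligodendrocyte precursors fell without resveratrol 3 (median -0.18, adjusted p = 0.00400), without vehicle 1 (-0.14, 0.0165), with a filter at 2 FPKM (-0.14, 0.0197) and, chosen after seeing the data, with the length and GC correction (-0.14, 0.0168), while without vehicle 2 the median was 0.0081 (range of adjusted p 0.00400 to 0.913). Without resveratrol 3, markers of claustrum, piriform cortex and amygdala (-0.16, 6.85e-04, range 6.85e-04 to 0.862) and meningeal fibroblasts (-0.11, 0.0111, range 0.0111 to 0.913) fell. Without vehicle 2, blood markers fell (-0.20, 0.0209, range 0.0209 to 0.999) and excitatory neuron markers rose (0.12, 0.0140, range 0.0140 to 0.975). With sample weights, astrocyte (-0.17, 0.0307, range 0.0307 to 0.854), endothelial (-0.19, 0.00520, range 0.00520 to 0.947) and meningeal fibroblast markers (-0.20, 0.0208) fell. That fit rests mostly on vehicle 1 and resveratrol 2. With vehicle 1 and 2 left out the endothelial median was 0.13. Camera's direction was opposite to the median for microglia, endothelial cells, meningeal fibroblasts and blood.

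The authors' own comparison called other genes. In the authors' deposited table, Eif3j1 had a log2 fold of 6.89 and a q-value of 0.839 and was not among those past 0.05. In the authors' deposited table, 101 genes had a q-value under 0.05, of which 15 were higher and 86 lower in resveratrol. Among genes past q 0.05, the largest log2 folds on the higher side of the authors' deposited table were those of the choroid plexus genes Kcne2 (2.02), Ttr (1.89), Folr1 (1.45), Aqp1 (1.32) and Kl (0.80), of Tinagl1 (0.97) and Sdf2l1 (0.76), and of the immediate early genes Arc (0.85), Junb (0.81) and Dusp1 (0.80). On the lower side of the authors' deposited table, again past q 0.05, stood Six3 (-1.40), a transcription factor of striatal neurons, Cfhr2 (-1.26), Zfhx3 (-1.25), Col1a1 (-1.18), Ly6c2 (-1.13), Kcnj10 (-1.11), the inward rectifier that clears potassium in astrocytes, Scd3 (-1.08), C4a (-1.07), Itga5 (-1.03) and Wipf3 (-1.01). Of the 101 genes in the authors' deposited table, 99 were tested here, all 99 with the same sign, 31 at an unadjusted p under 0.05 and 0 past the adjusted threshold in limma. Groups did not overlap in 15 of the 101 genes, 12 of them lower and 3 higher, in a set chosen for a difference between these groups.

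Across libraries, 66 of the 86 genes marked lower in the authors' deposited table had a vehicle 3 value nearer to the resveratrol mean than to the mean of vehicle 1 and 2. Kcnj10 had 23.8, 31.5 and 6.60 FPKM in vehicle 1, 2 and 3, against 11.3, 8.81 and 8.61 FPKM in the resveratrol libraries. Wipf3 had 25.4, 26.8 and 8.94 FPKM against 10.7, 9.84 and 9.95 FPKM. Col1a1 was different, at 1.28, 1.12 and 1.02 FPKM against 0.345, 0.473 and 0.702 FPKM. The median deviation of these 86 genes was 0.47 in vehicle 1, 0.75 in vehicle 2 and -0.42 in vehicle 3, and -0.42, -0.25 and -0.24 in the resveratrol libraries. Without vehicle 3 limma called 7 genes, 2 higher and 5 lower, with 1289 higher and 1066 lower genes at an unadjusted p under 0.05. The 7 were Kcnj10, Wipf3, Hist1h3a, Wnk1, Ptprz1, Pabpc1 and Eif3j1.

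**Figure D3:**
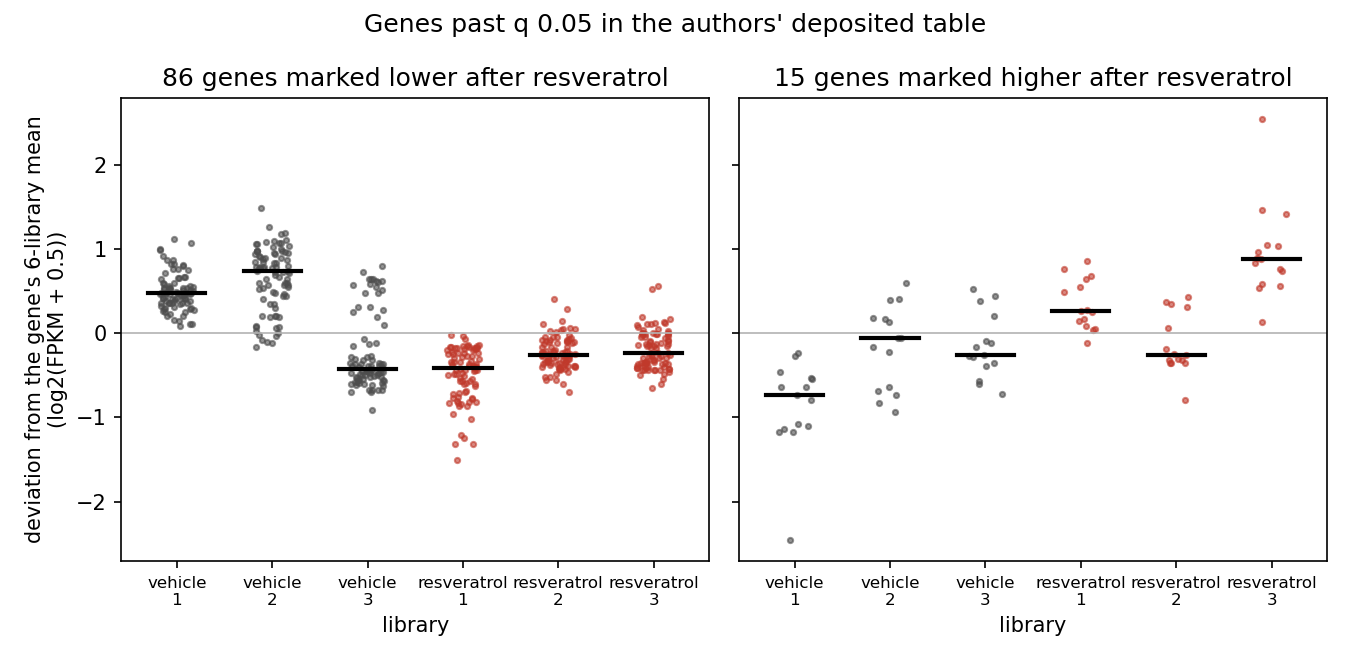
Each point is a gene past q 0.05 in the authors' deposited table, plotted by library as its log2(FPKM + 0.5) deviation from its 6-library mean, with black lines at the medians (left 86 lower genes, right 15 higher genes). For the lower genes vehicle 1 and 2 have medians of 0.47 and 0.75, and vehicle 3 lies at -0.42 beside the resveratrol libraries.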

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

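The call of Eif3j1 held under all 18 alternatives, with log2 fold changes from 3.61 to 5.94 and adjusted p up to 2.13e-04. The count of 1 gene (1 higher, 0 lower) stayed under the pseudocounts, filters, scalings, robust fit, threshold of 0.1 and, chosen after seeing the data, the length and GC correction. With a replicate block it was also 1 gene, with 7 pathway and 4 cell type lists. Same-numbered libraries deviated together with r across genes of 0.038, 0.148 and 0.184, and vehicle 1 followed resveratrol 2 (0.262) more, so the numbers were not taken as pairs. Sample weights gave 4927 genes (2889 higher, 2038 lower), but the estimate did not converge and put weights of 5.02 on vehicle 1 and 9.20 on resveratrol 2 against at most 0.556 elsewhere. Leaving out each library gave 1 to 7 genes, 1 to 3 higher and 0 to 5 lower, with 3 to 10 pathway lists and 3 to 6 cell type lists. The 7 genes (2 higher, 5 lower) came without vehicle 3, and 3 genes and 3 pathway lists without vehicle 2. Chosen after seeing the data, leaving out vehicle 1 and 2 gave 3 genes, 3 higher, where the lone vehicle library is assumed to vary like the others. The estimated correlation and fry each gave 0 pathway and 0 cell type lists, and a robust fit has no value for lists. In that fit without vehicle 1 and 2 the direction turned for oxidative phosphorylation (-0.15), ribosome (-0.14), chromatin modifiers (0.16), GABA signalling (0.0493), striatum (0.32), endothelial cells (0.13), glutamate receptors (0.14), NRF2 targets (-0.0592) and synaptic vesicles (0.10); chromatin modifiers also turned without vehicle 2 (0.0397), in a range over libraries left out from -0.156. In the authors' deposited table, 59 genes share the smallest p of 5.00e-05 and the smallest q of 0.0115, so the count of 0 past q 0.01 is set by that lowest p and says nothing on strength; chosen afterwards, 136 passed q 0.1 and 15 of 101 had groups without overlap. The cause of these shifts was not tested, and depth is unknown.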

Other observations

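Further gene groups, chosen after their values were seen, add to the picture of these cortices. Of 59 measured genes of replication-dependent histones, 38 were higher in resveratrol with a median log2 fold change of 0.09, and in camera their p was 0.0211 at the preset and 0.646 with an estimated correlation, unadjusted and for a list picked from these data in a limma fit. H3 genes went both ways, with Hist1h3a at 1.08 ± 0.23 (SE) and Hist1h3b at -0.74 ± 0.22. The mean deviation of the histone genes was -0.47 in vehicle 2, 0.35 in vehicle 3 and 0.28 in resveratrol 3. The RNA components of the RNA-processing enzymes RNase MRP and RNase P, Rmrp and Rpph1, had log2 fold changes of 0.59 ± 0.33 (SE) and 0.50 ± 0.32, and together took between 4.51% (vehicle 2) and 9.45% (resveratrol 3) of all listed FPKM. The spliceosomal RNA Rnu12 stood at the floor of 0.01 FPKM in vehicle 1 and 3 and at 49.6 FPKM in vehicle 2, against 34.7 to 59.9 FPKM in the resveratrol libraries. Since 95.7% of the 50-base words of Rmrp and 53.9% of those of Rnu12 occur in other genes, the values of both are uncertain.

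Y-linked genes were expressed in all 6 libraries, so each held male tissue. Ddx3y lay between 20.4 and 33.1 FPKM and Kdm5d between 8.61 and 10.2 FPKM. Among the 86 genes marked lower in the authors' deposited table, 20 had vehicle 3 on the side of the other vehicle libraries. At least 10% of the 50-base words occurred in other genes for 11 of the 18 of these with sequence data, against 2 of 65 of the rest. Fisher's exact test, chosen after seeing the data, gave a two-sided p of 1.27e-07. It treats rows as independent, while rows that share sequence can share reads, so this p overstates the evidence. Among the 11, Fam205a1, Srp54a and Zfp781 had 70.8%, 75.2% and 96.3%.

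Of the tests below, those on length and GC, on the position of vehicle 3 in the authors' genes, on the summed Eif3j rows, on tissue markers and on splits of gene counts were chosen after the results were seen; the test of a wrong label and the splits of list counts were set before theirs.

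In 66 of the 86 genes marked lower in the authors' deposited table (76.7%), vehicle 3 lay nearer to the resveratrol mean than to vehicle 1 and 2. After removal of a trend with transcript length and GC, the median log2 fold change of 82 of these genes was -0.55 (SD 0.19 over genes) against -0.57 before. An average trend over all genes thus accounted for little of their median fold change between groups. Length trends were opposed within vehicle (0.310, 0.474 and -0.502 in vehicle 1, 2 and 3) and could offset each other in its mean. The position of vehicle 3 against vehicle 1 and 2 was not measured after the correction. The test cannot exclude length or GC as a cause, since these genes were picked for a group difference in the same libraries. They were also long, with a median of 5407 bases against 3461.5 over the listed genes. That vehicle 1 and 2 stand apart for a reason other than treatment was not tested by the share of 76.7%, which only restates the pattern, and stays open. Of 100 genes with little shared sequence chosen without vehicle 3, vehicle 3 lay nearer to resveratrol in 100. With vehicle 1 or 2 as the library set aside the counts were 38 and 68, but those choices count vehicle 3 as vehicle. A wrong label on vehicle 3 may account for the pattern. Vehicle 1 and 2 standing apart for another reason would also give it, so this test cannot tell these apart. Vehicle 3 goes with its label in the called row Eif3j1 (0.0926 FPKM against 10.8 to 14.7 in resveratrol). The reads of that row are shared with Eif3j2 (18.2 against 1.74 to 7.78). Vehicle 3 also does so in Ccdc153 (2.02 against 0.573 to 0.968) and Col1a1 (1.02 against 0.345 to 0.702), picked for groups without overlap. Mean deviations of ependymal markers were 0.12, 0.19 and 0.24 in vehicle 1, 2 and 3, against -0.31, -0.12 and -0.13 in resveratrol. Heat shock, glycolysis and oligodendrocyte lists also had no overlap between groups in this mean. In oxidative phosphorylation, ribosome, striatal, chromatin and GABA lists, vehicle 3 instead lay on the side of resveratrol. These lists were called for a group difference that counts vehicle 3 as vehicle. Values with these limits do not exclude a wrong label, and it and an effect of resveratrol both stay open.

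The opposite shifts of the Eif3j1 and Eif3j2 rows, which carry the same locus in the deposited table, may come from reads shared between near-identical sequences. Their summed FPKM differed between groups by 0.147 SDs of the libraries within groups. A reassignment of the same reads between rows would give this if both rows were scaled by similar transcript lengths. Which transcripts each row holds is not settled, so that condition was not checked. That the vehicle libraries all sit at 0.0926 to 0.126 FPKM for Eif3j1 may reflect an assignment made per group, which was not tested. A true exchange of equal size between the transcripts stays open.

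Choroid plexus markers were higher and striatal markers lower in resveratrol, and differing amounts of adjoining tissue in the dissections are a candidate explanation. Within groups the 11 choroid plexus genes deviated together with a mean pairwise correlation across libraries of 0.603, and the 14 striatal genes with 0.900, where 95% of 10000 random lists matched on expression stayed under 0.136 and 0.146. Ttr ranged from 13.3 to 441 FPKM and Penk from 67.0 to 240 FPKM, though cortex also expresses Penk. Lists that mark no tissue also exceeded their random lists, with oxidative phosphorylation at 0.819, the ribosome at 0.716 and immediate early genes at 0.417. Ependymal markers, at -0.104, did not. The correlation therefore cannot single out tissue amounts. Genes under shared control would also deviate together, so an effect of resveratrol on either tissue stays open.

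With 3 libraries against 3 there are 10 splits, so no share can go under 0.1. The real split gave 1 gene and 4 of the 10 splits gave as many, with 1 as the highest of the others. At an unadjusted p under 0.05 the real split gave 329 genes and 6 splits gave as many. The highest count was 2158, for vehicle 1, vehicle 2 and resveratrol 2 against the rest. The libraries thus differ along lines other than the labelled groups, which a wrong label on vehicle 3 could also give. For pathway lists the real split gave 7, reached by 4 of the 10 splits, with 10 as the highest of the others. For cell type lists it gave 4, reached by 7 of the 10 splits, with 7 as the highest of the others.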
